A study of Mus musculus with 6 samples.

How the data were processed

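RNA sequencing values from 6 libraries of an immortalized mouse podocyte line were analysed, 3 from cells given a scrambled siRNA and 3 from cells given an siRNA against Tfeb. Sample titles gave the group and the replicate number of each library. Total RNA was isolated with TRIzol and libraries were made by a standard Illumina protocol, per the labels' protocols. The genome build was mm10, per the submitters' processing notes. The aligner, the read counter, the annotation release and the use of strand in counting are not given in the sources used here.

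The deposited table held FPKM values (fragments per kilobase of gene length, scaled to the depth of the library), with 1 column per library and the position and length of each gene, per the file headers. No column of another sample was present (0 unused). Each deposited FPKM value multiplied by the gene length was a whole multiple of 1 step in its library, for 100% of the values above 0 at a tolerance of 1e-06. Whole reads per gene and the depth of each library were therefore derived from the table. The depth by which the authors divided equalled the library's median-ratio size factor times the geometric mean of the 6 read totals (a ratio of 1 in each library), so the deposited FPKM values were already scaled between libraries. Derived totals were 20143910, 20604794 and 20610888 reads in scrambled siRNA replicates 1, 2 and 3 and 18062898, 20010130 and 19702898 reads in Tfeb siRNA replicates 1, 2 and 3. At this depth a gene at 1 FPKM rests on few reads when it is short, and read numbers are given for such genes; they cover counting error only. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise: the chi-square per gene of their derived reads was 4.40 to 8.16 between libraries of 1 group and 28.6 to 36.7 between groups.

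The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), over the 12257 of 53715 genes with a mean of 1 FPKM or more over the 6 libraries. Moderated tests used eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment, and a gene was called higher or lower at an adjusted p below 0.05. Every adjusted p given for a gene comes from this limma model unless another is named. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes; plain ratios of mean FPKM are given as x-fold. Errors are SD over n = 3 libraries, or the SE of the log2 fold change. The 4 MiT/TFE family transcripts were also tested with an exact two-sided permutation test, whose smallest possible p with 3 against 3 is 0.1.

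Before the data were examined, 23 gene lists were fixed for the tissue and the treatment, including markers of other cell types. The 22 lists with 3 or more tested members were compared with all other tested genes by camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Members were also counted after adjustment over the list alone. Camera with a correlation estimated from the residuals, and fry, which tests a list without reference to other genes, were run beside it. Genes named here follow a rule also fixed before the data were examined: the MiT/TFE family; the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a gene symbol of their own whose groups did not overlap; and in each list the 2 called members with the largest positive and the 2 with the largest negative change, or, where none was called, the 2 with the smallest p. Not every gene the rule picks is given. Genes whose values are given outside the rule, other than Keap1, are marked as chosen after their values were seen.

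The model had no block for the replicate number. Residual correlations between same-numbered libraries of the groups were 0.382, 0.129 and 0.166 for numbers 1, 2 and 3, all above 0.1, and each Tfeb siRNA library correlated best with the scrambled siRNA library of its number. For numbers 2 and 3 the lead was small. Tfeb siRNA replicate 2 correlated at 0.106 with scrambled siRNA replicate 3, and Tfeb siRNA replicate 3 at 0.0996 with scrambled siRNA replicate 2. The numbers were taken to pair the libraries, although the data set only number 1 clearly apart. This pairing comes from the data, since the titles only number the samples. A model with the number as a block was run as an alternative, and its value stands beside a result where it changed the call.

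GENCODE release M21 (mm10) served for 3' UTRs and for overlaps between genes. It held 12249 of the 12257 tested gene identifiers (99.9%), and 93.5% of tested genes had the same start and end there as in the deposited table, so the release used by the authors may differ. Heptamers (7-base words) were counted in the longest annotated 3' UTR of each gene, which need not be the one expressed in these cells, for the 10419 tested genes (85.0%) with a 3' UTR of 50 bases or more. For each of the 16194 heptamers present in 50 or more of these genes, the log2 fold change was regressed on the presence of the heptamer with UTR length and GC content as covariates, and the t values were divided by their SD over all heptamers. The share of a gene's 50-base words found in other genes and exon overlaps with other genes were computed from the same annotation. Genes with large shares are described as uncertain, because the way reads were divided among copies is not given in the sources used here. Adh7, Arsb, Atp6v0a2, Atp6v1h, Cox6c, Col4a3, Nid2, Csf2, Csf1r and Gapdh, among other genes named here, overlap exons on the opposite strand. Pfkm, Gata3, Pdia4 and Cd74 overlap exons on the same strand. Some reads of these genes may belong to the overlapping gene, on the opposite strand only if counting ignored strand.

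The procedure was tested on simulated reads for the 12257 genes with the depths of these 6 libraries. Of 50 genes changed at each size, 12% were recovered at 1.25-fold, 72% at 1.5-fold and 100% at 2-fold and at 4-fold, and 11 of 12027 unchanged genes were called. All simulated genes had a common dispersion (0.00699) and few were changed. The adjusted threshold was therefore stricter there than in the real comparison, where far more genes passed. Alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 FPKM, median-ratio, quantile and TPM scaling, eBayes without trend and robust eBayes, a replicate block, leaving out each library in turn, a 2-fold minimum, and other list tests. After the data were seen, 3 more were added: limma voom on the derived reads, a minimum mean of 10 derived reads, and leaving out genes whose 3' UTR holds 1 of 8 heptamers. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the sequence searches and figures.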

Results

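Podocytes are the epithelial cells that wrap the capillaries of the kidney glomerulus and form the outer layer of its filter. The cells here were an immortalized mouse podocyte line, grown at 33 °C with interferon gamma and 10% serum to proliferate and differentiated at 37 °C with 5% serum and 12 mg/ml type I collagen over 10 to 14 days. They were transfected with a short interfering RNA (siRNA) against Tfeb or with a scrambled siRNA as its control, with 3 libraries in each group. TFEB is a transcription factor of the MiT/TFE family that is known to activate lysosome and autophagy genes, and the comparison asks which transcripts differ when it is depleted. Libraries held 18062898 to 20610888 derived reads. Reads of mitochondrial genes made up 1.36% to 1.43% of the scrambled siRNA libraries and 1.44% to 1.57% of the Tfeb siRNA libraries. The first principal component, with 53% of the variance, separated the groups, and the second, with 19.3%, set replicate 1 of both groups apart from replicates 2 and 3.

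Tfeb itself (ENSMUSG00000023990, chromosome 17, 47737030 to 47792419, plus strand) was lower in each library given its siRNA. It stood at 1.80, 2.05 and 2.27 FPKM in scrambled siRNA replicates 1, 2 and 3 and at 0.639, 0.714 and 0.822 FPKM in Tfeb siRNA replicates 1, 2 and 3. The mean of the Tfeb siRNA group was 35.5% of that of the scrambled group (0.725 ± 0.0916 against 2.04 ± 0.233 FPKM, SD, n = 3; exact permutation p = 0.1, the smallest this design allows). Its log2 fold change was -1.05 (SE 0.13, limma adjusted p = 0.00148), from 723 reads in the scrambled group and 237 in the Tfeb siRNA group. Mitf, a family member known for its role in melanocytes and osteoclasts (ENSMUSG00000035158, chromosome 6, 97807052 to 98021349), also fell, from 2.29 ± 0.327 to 1.22 ± 0.155 FPKM (limma log2 fold change -0.69, SE 0.13, adjusted p = 0.00738). Tfe3, the most abundant member, had 6.06 ± 0.249 and 6.39 ± 0.0745 FPKM and did not pass the limma test (adjusted p = 0.364). Tfec lay below the filter, with 49 reads in the scrambled and 16 in the Tfeb siRNA group (exact permutation p = 0.1 for Mitf and Tfec and 0.2 for Tfe3). Of the 3 tested family members 0 rose, 2 fell and 1 did not pass, with the same numbers when adjusted over the list alone (camera adjusted p = 0.291, fry adjusted p = 0.00714). Tfeb, the target of the siRNA, is 1 of these 3, so the list tests partly restate its knockdown.

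**Figure D1:**
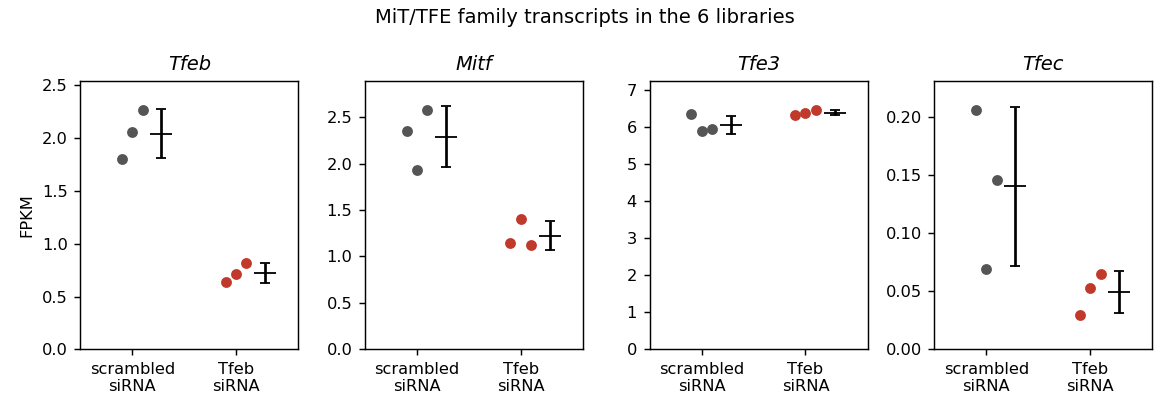
FPKM (vertical axes, each from 0) of the MiT/TFE family transcripts Tfeb, Mitf, Tfe3 and Tfec in the 6 libraries; points are libraries, and the black dash with its bar is the mean ± SD of 3. The Tfeb siRNA libraries lie below the scrambled libraries for Tfeb (0.639 to 0.822 against 1.80 to 2.27 FPKM) and for Mitf.

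Transcripts changed in both directions and in similar numbers. Of 12257 tested genes, 2075 were higher and 2005 lower after Tfeb siRNA, together 33.3%, and 72 of the higher and 103 of the lower genes changed by 2-fold or more on the log2(FPKM + 0.5) scale. The groups did not overlap for 5971 genes (48.7%, where chance gives 10%), and the median log2 fold change of all tested genes was 0.02.

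Among the genes with the largest increase were Nqo1, the NAD(P)H quinone reductase (chromosome 8, 107388225 to 107403206), and Adh7, an alcohol dehydrogenase (chromosome 3, 138217760 to 138233382). Nqo1 rose 4.90-fold, from 8.88 ± 2.27 to 43.5 ± 3.84 FPKM (limma log2 fold change 2.25, SE 0.17, adjusted p = 0.000337). Adh7 rose 4.71-fold, from 12.5 ± 1.84 to 58.6 ± 4.98 FPKM, and Taldo1, the transaldolase of the pentose phosphate pathway, rose 2.93-fold, from 36.0 ± 3.2 to 106 ± 5.82 FPKM. Stmn4, a stathmin family member, had 64 reads in the scrambled and 404 in the Tfeb siRNA group. The other genes of this rank were small RNAs with few reads: Mir344i (5 and 30), Mir7651 (1 and 12), Mir222 (0 and 10), Mir6939 (1 and 11), Mir6942 (2 and 8) and the mitochondrial glycine tRNA mt-Tg (4 and 22), so no fold is given for them. Mir6942 lost its call without 5 of the 6 libraries in turn (highest adjusted p = 0.113, without scrambled siRNA replicate 2), Mir6939 without scrambled siRNA replicate 1 or 3 (up to 0.0631) and Mir344i without Tfeb siRNA replicate 1 (0.0529). About 10.9% of the 50-base words of Taldo1 recur in a pseudogene, so part of its reads could not be placed with certainty.

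The largest decreases included 3 genes of the epidermal differentiation complex, the chromosome region that encodes proteins of the cornified envelope. Crct1 (chromosome 3, 93014205 to 93015687) fell 7.31-fold, from 6.55 ± 1.22 to 0.896 ± 0.640 FPKM (limma log2 fold change -2.41, SE 0.30, adjusted p = 0.00147), with 324 reads in the scrambled and 41 in the Tfeb siRNA group. Lce1h fell from 4.74 ± 1.35 to 0.552 ± 0.368 FPKM and Lce1g from 6.46 ± 2.16 to 1.49 ± 0.754 FPKM; both share sequence with other late cornified envelope genes (19.9% and 17.7% of 50-base words), which leaves the reads of each gene uncertain. Papss2, which makes the sulfate donor PAPS (chromosome 19, 32620005 to 32667187), fell 3.83-fold, from 27.0 ± 1.28 to 7.05 ± 0.871 FPKM. Vnn1, a pantetheinase, fell 3.73-fold to 4.49 ± 0.778 FPKM, and Synpo2l, a muscle actin-binding relative of synaptopodin, 3.80-fold to 2.54 ± 0.492 FPKM. Cyp4a12a, a fatty acid hydroxylase, had 80.2 ± 2.78 and 24.9 ± 5.13 FPKM, but 48.9% of its 50-base words recur in Cyp4a12b. Crygs, a lens crystallin, had 95 and 11 reads, Snord70 27 and 7, and the 5S ribosomal RNA copy n-R5s172 20 and 1. Snord70 lost its call without 4 of the 6 libraries in turn (highest adjusted p = 0.0606, without Tfeb siRNA replicate 2).

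Genes that fell and genes that rose differed in how often their 3' UTRs hold certain heptamers. An siRNA strand is known to lower transcripts whose 3' UTR pairs with its seed, the bases from position 2 to 8; the siRNA sequences are not given in the sources used here. Of 16194 heptamers, CTACATA had the lowest standardized t (-11.9): 34.4% of the 1107 genes that hold it were lower, against 15.9% of the other genes searched. TACATAA (-9.07) and GGCCATG (-7.07) came next. At the other end CGGAGAA (7.58), TCGGAGA (6.40) and TGTCACG (4.96) ranked highest, and 38.1% of the 333 genes that hold CGGAGAA were higher, against 17.4% of the others. After this ranking was seen, CTACATA, TACATAA, GGCCATG and GCCATGA were grouped as falling heptamers, and TCGGAGA, CGGAGAA, TGTCACG and GTCACGA as rising heptamers. They are 2 forms of the seed site of each strand of 2 siRNA duplexes assumed further below, not simply the most extreme words. GCCATGA ranked 8 from the lowest and GTCACGA (4.26) 11 from the highest. The shares that follow use the same fold changes, so they describe these sets and are no independent test of them. Of 3510 genes with a falling heptamer 25.7% were lower, where 14.0% were expected from genes of the same 3' UTR length, and of 980 genes with a rising heptamer 31.6% were higher, where 17.2% were expected. Both sets also held genes of the opposite direction: 14.6% of genes with a falling heptamer were higher, against 19.8% of the others, and 12.3% of genes with a rising heptamer were lower, against 18.5%. Of the 1864 lower genes searched, 961 hold no falling heptamer. Without the genes that hold any of the 8 heptamers, 1215 genes were higher and 926 lower of 8252 tested. Papss2 holds 2 falling heptamers, Adh7, which rose, holds 1, and Taldo1 holds 2 rising heptamers; Tfeb, Mitf and Nqo1 hold none in their longest annotated 3' UTR.

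**Figure D2:**
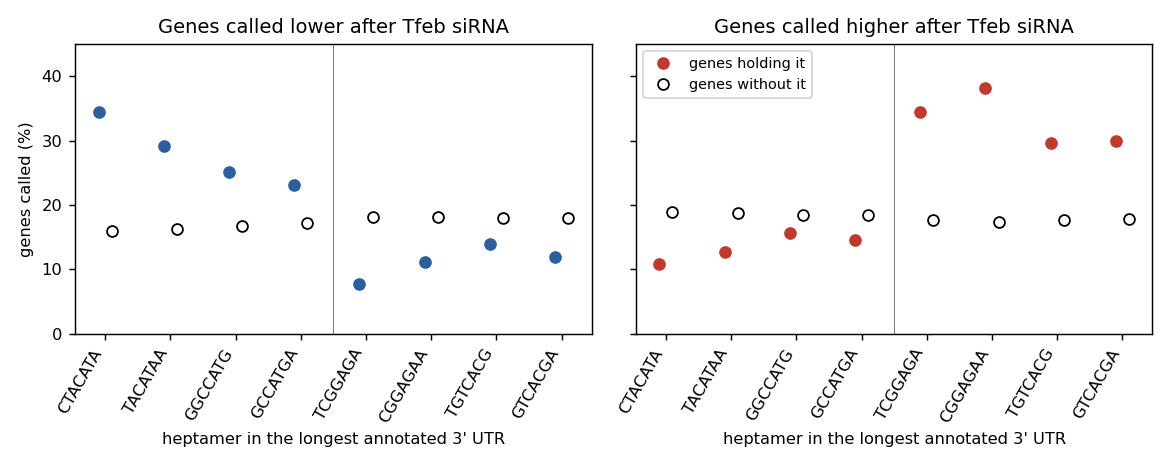
Share of searched genes called lower (left) and higher (right) after Tfeb siRNA, in percent, for genes whose longest annotated 3' UTR holds each of 8 heptamers (filled points) and for genes without it (open points). To the left of the grey line stand the 4 falling heptamers, led by CTACATA (34.4% against 15.9% lower), and to the right the 4 rising heptamers, with CGGAGAA at 38.1% against 17.4% higher.

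Lysosomal genes moved in both directions after Tfeb siRNA. Of 38 hydrolases and activators, 10 rose, 10 fell and 18 did not pass the test (11 and 11 adjusted over the list alone). Lgmn, the protease legumain, rose from 83.9 ± 3.96 to 135 ± 9.77 FPKM and Manba, beta-mannosidase, from 5.48 ± 0.0914 to 9.09 ± 0.579 FPKM. Arsb, the sulfatase arylsulfatase B (chromosome 13, 93771630 to 93943016), fell 3.47-fold, from 7.16 ± 0.222 to 2.06 ± 0.113 FPKM (limma log2 fold change -1.58, SE 0.07, adjusted p = 6.66e-05), and its 3' UTR holds all 4 falling heptamers. Ctsf, cathepsin F, fell from 2.96 ± 0.570 to 0.741 ± 0.136 FPKM. Of the 10 hydrolase genes that fell, 6 hold a falling heptamer, against 903 of all 1864 lower genes searched. Whether these shares differ was not tested. The list as a whole had no shared direction against other genes (mean log2 fold change -0.08, camera adjusted p = 0.754). Of all tested genes 33.3% passed the limma test, against 10 higher and 10 lower of the 38 here.

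Among 26 lysosomal membrane proteins 6 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.889). Slc17a5, the sialic acid exporter sialin, rose 1.43-fold, and Scarb2, the receptor that carries glucocerebrosidase to lysosomes, 1.29-fold. Gpnmb, a glycoprotein whose 3' UTR holds a falling heptamer, fell 1.96-fold, and Laptm4b fell 1.58-fold. Of 17 subunits of the V-ATPase, the proton pump of lysosomes, 3 rose and 5 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.584). Atp6v0a2 rose from 8.88 ± 0.829 to 14.4 ± 0.374 FPKM and Atp6v1b2 from 35.9 ± 2.99 to 46.0 ± 2.68 FPKM, although both hold a falling heptamer, while Atp6v0e fell 1.24-fold and Atp6v1h 1.22-fold. Without scrambled siRNA replicate 3 the adjusted p of Atp6v0e was 0.0503 and that of Atp6v1h 0.0612, and Atp6v1h also lost its call without Tfeb siRNA replicate 1 or 2. Among 22 genes of the Rag, folliculin and mTORC1 machinery, which controls TFEB at the lysosome, 4 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.522). Lamtor5 and Lamtor1, parts of the Ragulator complex, rose 1.49-fold and 1.37-fold, and Depdc5 and Fnip1 fell 1.52-fold and 1.31-fold; Fnip1 holds a falling and Lamtor1 a rising heptamer, and 14.5% of the 50-base words of Lamtor5 recur in pseudogenes.

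Of 48 autophagy genes 11 rose and 10 fell (14 and 10 adjusted over the list alone; camera adjusted p = 0.754). Atg12, which is conjugated to Atg5 in autophagosome formation, rose from 38.2 ± 2.88 to 63.5 ± 5.15 FPKM, although it holds 2 falling heptamers, and the receptor Calcoco1 from 18.6 ± 0.343 to 28 ± 1.82 FPKM. The cargo receptor Nbr1 fell from 21 ± 0.437 to 14.2 ± 0.231 FPKM and Pik3c3, the lipid kinase that starts autophagosomes, from 7.64 ± 0.594 to 5.32 ± 0.552 FPKM, and both hold 2 falling heptamers. Of the 10 autophagy genes that fell, 8 hold a falling heptamer, against 903 of all 1864 lower genes searched. Among the 29 members with none of the 8 heptamers, 8 rose and 1 fell (camera adjusted p = 0.203), whereas among 12 such V-ATPase subunits 0 rose and 5 fell (0.183). With the 5 lysosome and autophagy lists joined, 34 of 151 genes rose, 35 fell and 82 did not pass (39 and 36 adjusted over the list alone). Of all tested genes 33.3% passed, and whether more joined members changed than other genes was not tested. The joined list had no shared direction against other genes (mean log2 fold change -0.015, median 0.0002). Its p was 0.729 by camera at the preset correlation of 0.01 and 0.899 with an estimated correlation. The mean, which differs in sign from the median, was also positive without Tfeb siRNA replicate 2 (0.0046).

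**Figure D3:**
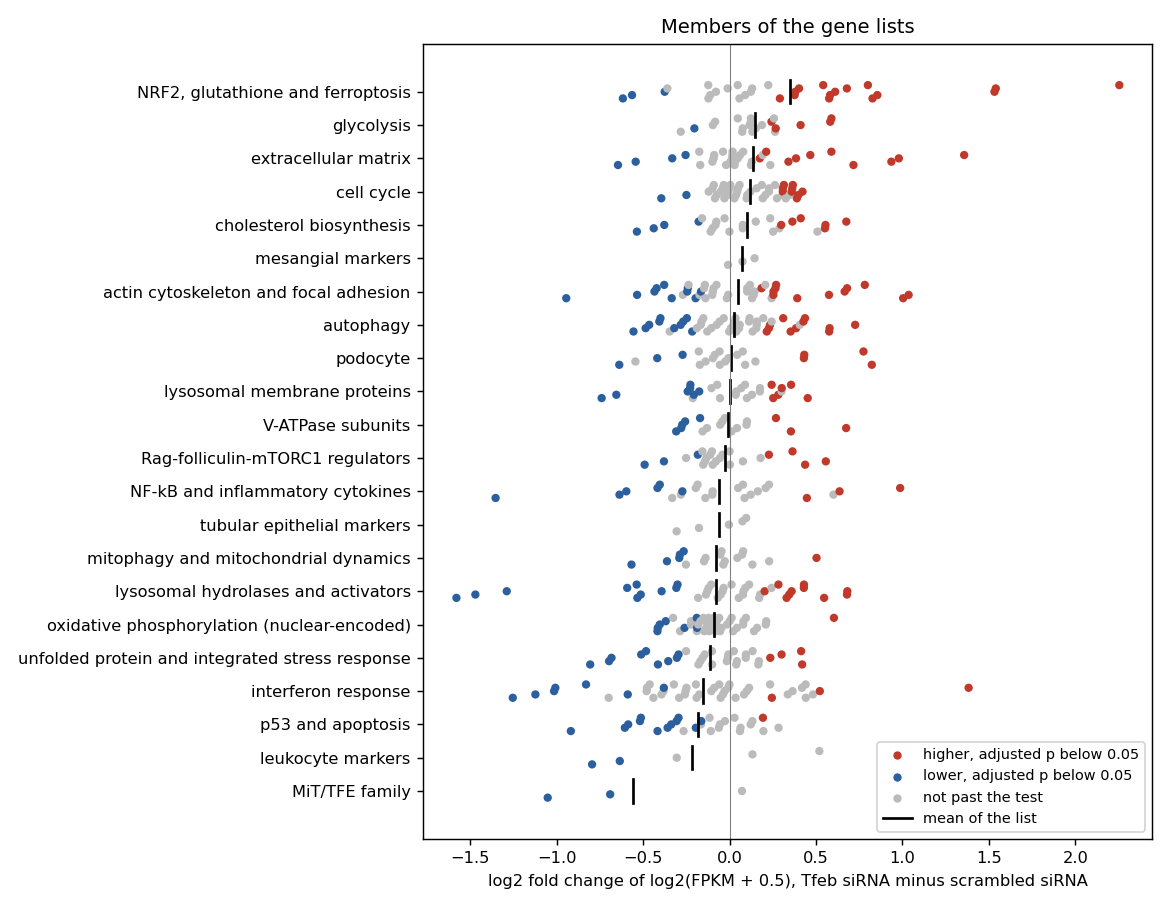
Log2 fold change on the log2(FPKM + 0.5) scale (horizontal axis, Tfeb siRNA minus scrambled siRNA) of each tested member of the 22 gene lists, ordered by the mean of the list (black bar). Red points were higher, blue points lower and grey points not past the limma test. The list of NRF2, glutathione and ferroptosis genes has the highest mean (0.35) and the MiT/TFE family, which includes the siRNA target Tfeb, the lowest (-0.56).

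Neither mitochondrial gene list passed the camera test. Of 18 genes of mitophagy and mitochondrial dynamics 1 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.351). Mfn1, a mitofusin, rose from 8.07 ± 0.758 to 11.6 ± 0.259 FPKM. Bnip3l, a mitophagy receptor, fell 1.49-fold, and Opa1, which fuses inner membranes, 1.30-fold; both hold a falling heptamer, and 23.4% of the 50-base words of Bnip3l recur in its pseudogene. Of 45 nuclear genes of oxidative phosphorylation 1 rose, 7 fell and 37 did not pass (1 and 6 adjusted over the list alone). Cox6c fell from 35.3 ± 3.90 to 26.2 ± 1.91 FPKM and Ndufb3 from 70.7 ± 4.44 to 52.9 ± 1.86 FPKM; Cox6c holds a falling heptamer. The list had a mean log2 fold change of -0.09 and missed the threshold (camera adjusted p = 0.0898). It passed with no filter on low values (0.0296), with TPM (0.0397), with the replicate number as a block (0.0220) and without Tfeb siRNA replicate 3 (0.0134, the lowest over the alternatives), and an estimated correlation gave p = 0.410 (adjusted p = 0.946, the highest). Of 20 glycolysis genes 5 rose and 1 fell (6 and 2 adjusted over the list alone; mean log2 fold change 0.15, camera adjusted p = 0.0898). The glycolysis list passed with no filter (0.0135), with TPM (0.0482) and with fry (0.0153), and its adjusted p ran up to 0.946 over the other alternatives. The glycolytic enzymes Gapdh, with 2.33 ± 0.0980 and 3.77 ± 0.393 FPKM, and Eno1, with 112 ± 1.98 and 168 ± 10.2 FPKM, share 27.2% and 72.2% of their 50-base words with copies. Both the level and the change of each are therefore uncertain, and the FPKM values should not be read as the true abundance of these transcripts. Pfkm, the muscle form of phosphofructokinase, was lower by 1.16-fold and lost its call without 4 of the 6 libraries in turn (highest adjusted p = 0.0616, without scrambled siRNA replicate 2).

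Genes of the NRF2 response, glutathione and ferroptosis rose more often than they fell. NRF2 is the transcription factor that activates antioxidant and detoxifying enzymes. Of 30 members 15 rose, 3 fell and 12 did not pass, with the same numbers adjusted over the list alone. Nqo1 and Taldo1, given above, rose most. Other members singled out after their values were seen were Srxn1, the sulfiredoxin (12.4 ± 0.367 to 36.9 ± 2.89 FPKM), Txnrd1, thioredoxin reductase (63.9 ± 5.38 to 111 ± 0.647 FPKM), Gclm, a subunit of the enzyme that starts glutathione synthesis (17.4 ± 1.53 to 28.1 ± 2.43 FPKM), and Nfe2l2, which encodes NRF2 (22.3 ± 0.581 to 33.7 ± 2.40 FPKM), all called higher. Gpx1, a glutathione peroxidase, fell from 205 ± 11.3 to 134 ± 14.7 FPKM although it holds a rising heptamer, and Ncoa4, the receptor for ferritin degradation, from 10.2 ± 0.499 to 6.76 ± 0.307 FPKM, with 2 falling heptamers. The list passed the camera test (mean log2 fold change 0.35, adjusted p = 0.0195) and fry (adjusted p = 0.00767), but not with an estimated correlation (p = 0.210, adjusted p = 0.946). Its mean was 0.35 also among the 19 members with none of the 8 heptamers, where camera gave an adjusted p of 0.0564.

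The p53 and apoptosis list leaned the other way. Of 27 members 1 rose, 12 fell and 14 did not pass, with the same numbers adjusted over the list alone. Perp, a p53 target and desmosome component (chromosome 10, 18845020 to 18857073), fell from 58.2 ± 0.437 to 30.5 ± 0.630 FPKM (limma log2 fold change -0.92, SE 0.04, adjusted p = 8.64e-05), and the survival factor Mcl1 (chromosome 3, 95658788 to 95663176) from 88.5 ± 4.28 to 58.0 ± 3.85 FPKM. Members that fell included inhibitors of apoptosis (Mcl1, Bcl2) and promoters of it (Perp, Fas). Bcl2 and Fas, named after their values were seen, fell from 10.2 ± 0.113 to 7.01 ± 0.221 FPKM and from 22.6 ± 2.79 to 17.5 ± 1.48 FPKM. Aen, a p53-induced nuclease, was higher by 1.15-fold and lost its call without 3 of the 6 libraries in turn (highest adjusted p = 0.0849, without scrambled siRNA replicate 3). The list passed the camera test (mean log2 fold change -0.18, adjusted p = 0.0195) and fry (adjusted p = 0.00324), but with an estimated correlation its p of 0.0306 became an adjusted p of 0.673. Of the 12 members that fell 8 hold a falling heptamer, Perp and Mcl1 among them, against 903 of all 1864 lower genes searched. Over the 14 members with none of the 8 heptamers the mean was -0.09 (camera adjusted p = 0.214).

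Podocyte genes changed in both directions. Of 21 tested members 4 rose, 3 fell and 14 did not pass, also when adjusted over the list alone. Podxl, the podocalyxin of the podocyte surface (chromosome 6, 31519488 to 31563981), rose 1.82-fold, from 8.72 ± 0.303 to 15.8 ± 1.43 FPKM. Synpo, the synaptopodin of foot process actin (chromosome 18, 60593973 to 60660142), fell 1.56-fold, from 74.4 ± 5.35 to 47.6 ± 1.85 FPKM (limma log2 fold change -0.64, SE 0.07, adjusted p = 0.000876), although it holds a rising heptamer. Col4a3, a collagen chain of the glomerular basement membrane, fell from 7.20 ± 0.470 to 5.27 ± 0.516 FPKM and holds 2 falling heptamers. The mean of the list was above 0 (0.006), its median below 0 (-0.06), and camera did not set it apart (downward, adjusted p = 0.754). Another 14 podocyte genes lay below the filter and were not tested; 5 had a higher and 9 a lower mean FPKM after Tfeb siRNA, with 1113 reads together in the scrambled and 896 in the Tfeb siRNA group. Among them Nphs1 had 96 and 25 reads, Wt1 195 and 132, Magi2 167 and 234, and Thsd7a 138 and 222 (named after their values were seen).

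Of 42 genes of the actin cytoskeleton and focal adhesions 12 rose and 10 fell (12 and 13 adjusted over the list alone; camera adjusted p = 0.889; mean 0.05, median -0.01). Actg2, smooth muscle gamma-actin, rose from 2.47 ± 0.243 to 5.61 ± 0.881 FPKM and Itgb5, integrin beta 5, from 79.9 ± 5.51 to 161 ± 7.21 FPKM. Lims1, the integrin adaptor PINCH, fell 1.94-fold to 25.9 ± 1.2 FPKM and holds 2 falling heptamers. The kinase Pak1 fell 1.65-fold, a call lost without scrambled siRNA replicate 1 or 3 (adjusted p up to 0.0553). Of 34 extracellular matrix genes 10 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.291). Col1a1, a chain of type I collagen (chromosome 11, 94936224 to 94953042), rose 2.88-fold, from 2.54 ± 0.382 to 7.31 ± 1.14 FPKM, and the proteoglycan Bgn 2.35-fold to 2.91 ± 0.274 FPKM. Nid2, a basement membrane linker, fell from 43.4 ± 4.40 to 27.5 ± 1.20 FPKM, and the collagen cross-linking enzyme Lox from 45 ± 2.95 to 30.9 ± 4.78 FPKM.

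Of 43 cell cycle genes 9 rose and 2 fell (7 and 1 adjusted over the list alone; mean log2 fold change 0.12, camera adjusted p = 0.173). The list passed without Tfeb siRNA replicate 3 (adjusted p = 0.0102) and with no filter on low values (0.0167), and its adjusted p ran up to 0.946 over the other alternatives. Uhrf1, which maintains DNA methylation, rose 1.36-fold and Cenpf, a kinetochore protein with a falling heptamer, 1.41-fold, while cyclin D1 (Ccnd1), which also holds one, fell from 261 ± 16.0 to 198 ± 6.48 FPKM and cyclin E1 (Ccne1) by 1.20-fold. Only Ccnd1 of these kept its call with any library left out: the highest adjusted p was 0.0755 for Uhrf1 (3 of the 6 left-out libraries ended its call), 0.0710 for Cenpf (4 of 6) and 0.107 for Ccne1 (5 of 6), and 18.9% of the 50-base words of Uhrf1 recur in pseudogenes. Of 31 genes of the unfolded protein and integrated stress responses 4 rose and 9 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.309). The endoplasmic reticulum chaperones Hspa5 and Pdia4 rose 1.34-fold each, from 222 ± 5.54 to 298 ± 15.6 FPKM and from 119 ± 4.41 to 160 ± 12.2 FPKM. Atf6, a sensor of unfolded proteins with 2 falling heptamers and 1 rising heptamer, fell from 18.2 ± 0.253 to 10.2 ± 0.726 FPKM. Atf3, a stress-induced factor, was lower by 1.63-fold and lost its call without 4 of the 6 libraries in turn (highest adjusted p = 0.117, without scrambled siRNA replicate 3). Of 24 cholesterol synthesis genes 6 rose and 4 fell (9 and 5 adjusted over the list alone; camera adjusted p = 0.522). Ebp fell 1.46-fold and Lss, with a falling heptamer, 1.40-fold.

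Interferon response genes split. Of 44 members 3 rose, 7 fell and 34 did not pass (2 and 7 adjusted over the list alone). Bst2, the virus-tethering protein tetherin (chromosome 8, 71534255 to 71537456), rose 2.52-fold, from 126 ± 45.4 to 317 ± 30.01 FPKM (limma log2 fold change 1.38, SE 0.22, adjusted p = 0.0041), and the class I histocompatibility gene H2-K1 from 110 ± 10.9 to 157 ± 9.76 FPKM. The interferon-induced genes Ifit3 and Ifit3b were lower, at 91.9 ± 26.4 against 37.7 ± 6.77 FPKM and 14.3 ± 4.40 against 6.21 ± 1.33 FPKM; they share 51.2% and 45% of their 50-base words with copies, mainly each other, so the reads of each are uncertain, and 8.11% of those of H2-K1 recur in related genes. The list did not pass (mean log2 fold change -0.15, camera adjusted p = 0.215) and rested on single libraries: without scrambled siRNA replicate 2, which had the highest Bst2, Ifit3 and Ifit3b of its group, the mean was 0.02 with 9 members higher and 7 lower, and without scrambled siRNA replicate 3 the list passed at an adjusted p of 0.00337 with 2 higher and 11 lower. Of 24 genes of NF-kB and inflammatory cytokines 3 rose and 6 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.522). Lcn2, the iron-binding lipocalin, rose 2.57-fold to 2.25 ± 0.501 FPKM and the chemokine Ccl7 1.62-fold, a call lost without 4 of the 6 libraries in turn (highest adjusted p = 0.0752, without Tfeb siRNA replicate 3). Csf2, which encodes GM-CSF, fell 3.93-fold to 0.545 ± 0.248 FPKM on 107 and 25 reads, and complement C3 1.62-fold to 4.26 ± 0.457 FPKM.

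Markers of other kidney and blood cells were low with few exceptions. Of 12 endothelial markers 11 lay below the filter, 1 with a higher and 9 with a lower mean FPKM after Tfeb siRNA and 1 without reads, together 1398 reads in the scrambled and 1078 in the Tfeb siRNA group. Among them Flt1 had 645 and 586 reads, Kdr 109 and 100, Vwf 148 and 31, and Esam 128 and 61 (named after their values were seen). The remaining one, Ehd3, which kidney endothelium expresses, was lower, at 9.74 ± 0.949 against 11.8 ± 0.477 FPKM (limma adjusted p = 0.0368), a call lost without 5 of the 6 libraries in turn (highest adjusted p = 0.107, without scrambled siRNA replicate 2); with 1 member the list was not tested. Of 3 tested mesangial markers and 5 tested tubular markers none passed the limma test, also when adjusted over each list alone (camera adjusted p = 0.754 for both). Serpine2 had 6.02 ± 0.115 and 6.72 ± 0.437 FPKM and Gata3 1.21 ± 0.278 and 1.30 ± 0.221 FPKM. The endocytic receptors of the proximal tubule Lrp2, at 52.5 ± 5.43 and 46.3 ± 3.44 FPKM, and Cubn, at 1.18 ± 0.149 and 0.855 ± 0.0691 FPKM, did not pass either (adjusted p = 0.179 and 0.127). Of 5 tested leukocyte markers 0 rose, 2 fell and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 0.314, fry adjusted p = 0.00767). Csf1r, the receptor for macrophage colony-stimulating factor, fell from 4.25 ± 0.15 to 2.24 ± 0.133 FPKM and holds a falling heptamer, and Cd74, the invariant chain of class II histocompatibility molecules, from 85.9 ± 3.71 to 55.2 ± 3.71 FPKM.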

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

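Of the alternatives below, voom on derived reads, the minimum of 10 derived reads and leaving out genes with a heptamer were chosen after the results were seen. The planned count models were not run, because the deposited values are FPKM; limma voom on derived reads took their place. Across the alternatives for which Tfeb was tested its log2 fold change ran from -1.52 (voom) to -0.82 (pseudocount 1), with adjusted p from 3.65e-05 to 0.00942, all past the threshold; with a filter of 5 FPKM Tfeb was not tested. No gene called in the main comparison was called in the opposite direction under any alternative with gene values. With a 2-fold minimum 72 genes were higher and 103 lower, since fewer genes meet both thresholds. Without genes that hold a heptamer 1215 of 8252 were higher and 926 lower, with fewer genes tested; genes that rose were 56.7% of calls there, against 50.9% in the main comparison, 42.6% with TPM and 44.0% with voom. Leaving out 1 library gave 1412 to 1703 higher and 1371 to 1720 lower genes.

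The 2 lists past the camera threshold became 5 without a filter, 4 with TPM and 5 with fry, where the MiT/TFE family, which includes Tfeb, was among them. They became 0 with an estimated correlation, 0 without heptamer genes and 2 to 4 with 1 library left out. Apart from fewer genes or samples, the cause was not tested. The replicate block, which follows the pairing described with the methods, gave 2542 higher and 2386 lower genes and 3 lists; the oxidative phosphorylation list was added (adjusted p = 0.0220), and the block changed no other call among the lists and the genes chosen by rule.

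Means near 0 changed sign. The joined lysosome and autophagy list was at 0.00806 with a filter of 5 FPKM (p = 0.881 by camera at the preset correlation), at 0.0214 without heptamer genes (p = 0.938) and between -0.0344 and 0.00458 with 1 library left out; its p ran from 0.473 to 0.970 over the alternatives. Lysosomal membrane proteins were at -0.00119 without a filter, -0.00263 at 5 FPKM, -0.00807 with quantile scaling, -0.0249 with TPM, -0.0305 with voom and -0.0174 to 0.0276 with 1 library left out. The podocyte list was at -0.0255 without a filter, -0.0136, -0.00562, -0.0594 and -0.0255 under the next 4 of these settings and -0.0267 to 0.0402 with 1 library left out. Hydrolases were at 0.0135 with the filter of 5 FPKM and autophagy at -0.00387 with voom. With 1 library left out V-ATPase subunits ran from -0.0454 to 0.0205, the interferon list from -0.281 to 0.0200 and Gata3 from -0.0373 to 0.196. The cause of these changes was not tested.

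Of 95 genes besides Tfeb chosen by rule to be named, 77 kept direction and side of the threshold in all alternatives that tested them, 15 lost their call at least once, mostly with 1 library left out, where fewer samples remain, Cubn and Lrp2 passed with voom and Cubn also without trend. At this depth and number of libraries 72% of simulated genes changed by 1.5-fold were called. Few simulated genes were changed, whereas 33.3% of real genes passed, which loosens the adjusted threshold. The simulated share therefore does not measure how often small changes were missed here.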

Other observations

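All tests of gene families and the members named for them, and the tests of the second strand of the Tfeb duplex, of the nontargeting duplex and of scrambled siRNA replicate 2, were chosen after results were seen. Among 253 families of genes with a shared symbol root, none differed from other genes at an adjusted p below 0.05 by camera, although 34 of them did at an unadjusted p below 0.05. Of 268 zinc finger genes (Zfp), the largest family tested, 64 were higher and 11 lower, or 45 and 10 with TPM (mean log2 fold change 0.12, adjusted p = 0.213; p = 0.434 with an estimated correlation). Of 10 splicing factors of the Srsf family 6 were higher and 0 lower, or 5 and 1 with TPM, among them Srsf7 at 29.8 and 38.6 FPKM (log2 fold change 0.37, SE 0.05, adjusted p = 0.00257) and Srsf2 at 35.9 and 44.9 FPKM. Of 171 genes with the symbol root Slc, mainly solute carriers, 26 were higher and 55 lower, or 20 and 58 with TPM (mean -0.12, camera adjusted p = 0.121). The lower ones were led by Slc1a6, a glutamate transporter, at 5.64 and 1.93 FPKM and Slc31a2, a copper transporter with 2 falling heptamers, at 31.3 and 13.7 FPKM. Of 13 cytochrome P450 genes (Cyp) 0 were higher and 4 lower, or 6 lower with quantile scaling and 5 with TPM (mean -0.38, adjusted p = 0.121); Cyp4b1 fell from 5.60 to 2.69 FPKM. The means of these 4 families kept their direction under quantile and TPM scaling. They also did under median-ratio scaling, which could hardly change them because the deposited values were already scaled that way.

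The heptamers of genes that fell and rose were weighed as seed matches of the siRNAs, that is, off-target effects of the duplexes. The lowest standardized t of all heptamers, -11.9 for CTACATA, belongs to a word that occurs in Tfeb transcripts. The highest, 7.58 for CGGAGAA, lies beyond the bound set before it was seen (4.7 to either side). Part of the lower genes may be seed targets of the Tfeb siRNA, and part of the higher genes seed targets of the scrambled siRNA released in the other group. Both criteria have limits. Tfeb transcripts hold 3939 heptamers, against 16194 tested, so a word picked at random would often occur there. TTTTTTT (4.73), a seed site of neither duplex given below, also passed the bound, so passing it does not by itself mark a seed match. The word CCATGGCCATGCTACATAT (chromosome 17, 47786492 to 47786510, coding exon 2 of 8 of Tfeb-201, in 4 of 15 annotated Tfeb transcripts) would pair with a duplex whose other strand has the seed site GGCCATG, at -7.07, and a nontargeting duplex in wide use, its sequence taken from general knowledge, has the seed sites TCGGAGA and TGTCACG, the lower at 4.96; neither duplex is given in the sources used here. Genes with a falling heptamer exceeded the number expected at their 3' UTR length by 412 of 1864 lower calls (22.1%). Genes with a rising heptamer did so by 141 of 1878 higher calls (7.52%). The heptamers were chosen on these same data, so the excesses describe them and are no independent test. On these numbers most calls stay open between loss of TFEB, its indirect effects and effects of the duplexes that leave no such match. A seed match in the 3' UTR of Mitf is argued against, since its longest annotated 3' UTR holds 0 of the 4 falling heptamers; loss of TFEB as the source of the lower Mitf was not tested.

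The rise of the NRF2, glutathione and ferroptosis list was set against 3 explanations. Release of Nfe2l2 from the scrambled siRNA through its 3' UTR is argued against by 0 rising heptamers there, and seed matches in the members' own 3' UTRs by the mean of 0.353 over the 19 members without a heptamer, against 0.352 over all 30. What stays open is a lower Keap1 transcript, which would release NRF2, since its log2 fold change of -0.112 (SE 0.08, adjusted p = 0.299) lies above the bound of -0.2 by less than 2 SE; a response to loss of TFEB; a response to either duplex through another gene; and, since the call was lost with an estimated correlation (adjusted p = 0.946), the shared variation of the members. The last 3 were not tested further.

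Interferon genes changed in both directions and differed between scrambled siRNA libraries, so replicate 2 of that group was weighed as the sole source. That is argued against: without it 16 members passed the threshold, 9 higher and 7 lower, with Bst2, Oas1a and Irf7 among those higher and Ifit3, Gbp2 and Iigp1 among those lower (all but Bst2 and Ifit3 chosen after their values were seen). Seed matches in the members' own 3' UTRs are argued against too, since 0% of the 10 called members hold a heptamer that fits their direction. A different exposure to interferon gamma, which the labels give as part of the growth medium, may remain as a source of spread between libraries, as may a response to the duplexes or to loss of TFEB; none of these was tested.

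The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split mixes the siRNA groups, so the group difference widens the spread within its sides. Few called genes are thus built into those splits, and their low counts cannot decide whether chance gave the real ones. As many genes in 1 direction as in the real split (2075 higher, 2005 lower) came from 1 of the 10 splits, the real one, and the highest other gave 1 gene by limma. As many lists as the real 2 came from 6 of the 10 splits, the highest other giving 5, and a camera p for the joined lysosome and autophagy list as small as the real 0.729 came from 9 of the 10, the smallest other being 0.0223. Of the splits that part all 3 numbered pairs, the 3 others gave 0 genes at an adjusted p below 0.05 and 102 to 164 at an unadjusted p below 0.05, and 4, 1 and 1 lists.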
